A study of Malus domestica with 34 samples.

How the data were processed

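RNA was sequenced from leaves and roots of apple seedlings (Malus domestica) of the 'Golden Delicious' doubled haploid line GDDH18, a line with identical chromosome copies. Per the labels' protocols, seeds were sown in 3 blocks a week apart, and each block was a biological replicate. Plants were 12 weeks old when the regimes began. Of these, 64 were kept near 80% soil water content, and 61 went through cycles of 3 weeks at 45% and 3 weeks of rewatering. Libraries were made with a stranded mRNA kit and sequenced as 100 bp pairs, per the labels' protocols. The number of plants behind a library was not given in the sources used here.

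The deposited table held estimated counts per gene, already in whole numbers, for 52311 gene identifiers in 34 libraries, so no rounding was needed. The submitters' processing notes list FastQC, Salmon, DESeq and DESeq2 without versions. Salmon estimates counts from reads matched to transcripts and divides reads shared by similar transcripts, so near-identical gene copies are uncertain. The genome build, the annotation and the settings were not given in the sources used here. Totals ran from 25974815 to 68239819 counts per library, and 8708 identifiers had no count in any library.

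None of the identifiers (0 matches) appeared in the RefSeq gene table of the GDT2T_hap1 assembly, and the deposited table does not pair them with names. The comparisons, the alternatives, the rule for naming genes and a series of gene lists had been fixed before the data were examined. The lists needed names and could not be run. For the same reason at most 2 identifiers that rose and 2 that fell are given per comparison, and no coordinates are given.

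Groups were defined by tissue, watering regime and sampling. The libraries of a group came from separate sowings, so p-values rest on biological replicates. Each had 3 libraries, except the root groups of the next year with 2 each. Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust dispersions, then glmQLFTest) in R 4.3.3. Scaling was by TMM, and low counts were removed by filterByExpr. All groups of a tissue were fitted together, so they shared an estimate of the spread; all 34 libraries were fitted together for leaf against root. Benjamini-Hochberg adjusted p under 0.05 counted as called. The standard error of a log2 change was its size divided by the square root of the F statistic. Sets of genes were tested with camera in limma 3.58.1, given the edgeR counts and dispersions instead of the log2 CPM that had been planned. The preset correlation was 0.01, and the estimated correlation was the alternative. Scores per library used log2 CPM with a prior count of 2. The sets were defined after the data were seen, from the calls of the first leaf comparison and from next-year tissue differences. The rule for naming genes asked for an adjusted p under 0.05, a mean log2 CPM of at least 1 and groups that did not overlap, and then took the 2 largest changes in each direction. For the change from the first to the third drought it took the 2 largest differences past the test in each direction, at any mean level. These 4 are summarised without their identifiers, because their calls did not hold under many alternatives. For a drought comparison with no called gene the rule gave up to 3 genes of smallest p, all with an adjusted p of 1, and these are left out.

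The replicate number marks the sowing block per the labels, so libraries with the same number are paired. Deviations of same-numbered libraries from their group means correlated between 0.16 and 0.64 in 4 of the 5 samplings with 3 such pairs, the exception being root after the first drought, at -0.71 to -0.26. The next-year roots share only block 3 between the regimes, and with 2 libraries per group their correlation says nothing about pairing. The fit without the block was the main design, and the fit with it an alternative. No pair of libraries agreed within sampling noise, since the lowest chi-square per gene over 273 pairs was 13.9.

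The steps were tested on simulated counts made from the real means, library sizes and dispersions, with 67 genes changed 2-fold, 67 changed 4-fold and 66 changed 8-fold per comparison. The changed genes were drawn from the more abundant genes, so the shares called do not cover scarce genes. Each gene had the same dispersion at every sampling, genes varied independently, and no block effect was simulated. Among 31953 tested leaf genes, edgeR called 38.8%, 82.1% and 95.5% of the changed genes for the first drought. The shares were 35.8%, 86.6% and 98.5% for the third, and 37.3%, 83.6% and 90.9% for the next year. Among 33178 tested root genes it called 14.9%, 82.1% and 97.0% for the first drought, 20.9%, 80.6% and 90.9% for the third, and 4.48%, 55.2% and 92.4% for the next year. Unchanged genes called by edgeR numbered 5 to 9 per comparison, and 43 to 62 by DESeq2. Alternatives covered the scaling, the filters, DESeq2 1.42.0, the block, the libraries fitted, the dispersion, a fold threshold and leaving out each library. Counting intervals are exact Poisson intervals at 95% and cover counting error only.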

Results

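The data comprise 34 libraries, 18 from leaf and 16 from root, of seedlings kept well-watered or taken through repeated drought. Samples were taken after the first drought, after the third drought and in the following year, after a winter and before any new stress. The comparisons ask how leaves and roots respond to a first drought, whether the response recurs, and whether a trace persists into the next year. Each group held 3 libraries, and the root groups of the next year held 2. Leaf libraries held between 25974815 and 68239819 counts and root libraries between 29963017 and 60194325.

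After the first drought, leaf expression differed between the regimes over a broad set of genes. Of 32307 genes tested, 1657 were higher and 2155 lower in drought leaves by edgeR's quasi-likelihood test (adjusted p under 0.05). The median called gene changed 2.13-fold among those that rose and 2.12-fold among those that fell. With the 12 and 5 of them that had a group at 0 counts set to a bound from a floor of 3 counts over the group, the median log2 changes were 1.09 and 1.08 in size. Of the called genes, 268 rose and 329 fell by at least 4-fold. The genes that rose took 2.91% ± 0.405 of all counts in well-watered leaves (SD, n = 3) and 5.93% ± 0.315 in drought leaves (n = 3). The genes that fell took 7.77% ± 0.806 and 4.01% ± 0.442.

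MD06G1227300 was at 0.699 ± 0.433 CPM in well-watered leaves and 69.2 ± 37.5 CPM in drought leaves (SD, n = 3 each), a log2 change of 6.52 (SE 1.12, edgeR adjusted p = 0.0036). In root libraries this gene had group means from 37.9 to 86.9 CPM. MD08G1062400 rose from 3 counts over the well-watered libraries to 735 over the drought libraries, a ratio of 243 (95% counting interval 82.8 to 1180, edgeR adjusted p = 0.0124). MD17G1140600 fell from 6.85 ± 4.27 CPM to a single count over the drought libraries, a ratio of 778 in favour of the well-watered leaves (interval 139 to 30800, edgeR adjusted p = 0.0181). MD09G1154000 fell from 5.28 ± 4.08 to 0.0594 ± 0.0521 CPM, a log2 change of -6.30 (SE 1.38, edgeR adjusted p = 0.0112). As the rule for naming required, every drought library lay above every well-watered one for the first pair, and below for the second. At the third sampling, MD06G1227300 was at 22.7 ± 6.12 CPM in well-watered and 18.3 ± 14.4 CPM in drought leaves, MD08G1062400 at 2.9 ± 1.22 and 5.31 ± 5.77 CPM, MD17G1140600 at 25.6 ± 23.9 and 14.7 ± 10.7 CPM, and MD09G1154000 at 23.7 ± 22.4 and 17.4 ± 6.98 CPM. The log2 changes there were -0.49, 0.75, -1.05 and -0.70 (edgeR adjusted p = 1 for each), so the last 3 had the sign of the first drought. MD08G1062400 lost its call without well-watered block 1 (adjusted p = 0.0589), and MD17G1140600 without drought block 1, 2 or 3 (adjusted p = 0.0581, 0.0731 and 0.0595).

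Drought and well-watered leaves did not overlap for 31.1% of the tested genes, where chance gives 10%. The number of called genes depended on single libraries: it was 1461 without well-watered block 1, 2201 without drought block 1 and 1670 without drought block 2. Fitting these 6 libraries alone called 1182 genes, of which 1020 were among the 3812, and DESeq2 called 5843.

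After the third drought, no leaf gene passed the test, and the genes called after the first drought did not show the same direction as a set. Among the 1657 genes that had risen, the median log2 change was -0.19, and among the 2155 that had fallen it was 0.19. Of the called genes, 84.6% had the opposite sign at the third drought. The camera test placed the first set below other genes (adjusted p = 1.96e-21), but its adjusted p = 0.12 with an estimated correlation, and placed the second set above them (adjusted p = 1.7e-28, adjusted p = 0.12 with an estimated correlation). Over all genes, edgeR called 0, and DESeq2 also called 0. An unadjusted p under 0.05 was reached by 727 genes, or 2.25%, below the share of 0.05 that arises with no effect. The other comparisons of the regimes at a single sampling without edgeR calls, in leaf or root, also lay below it, at 1.01% to 2.79%.

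**Figure D1:**
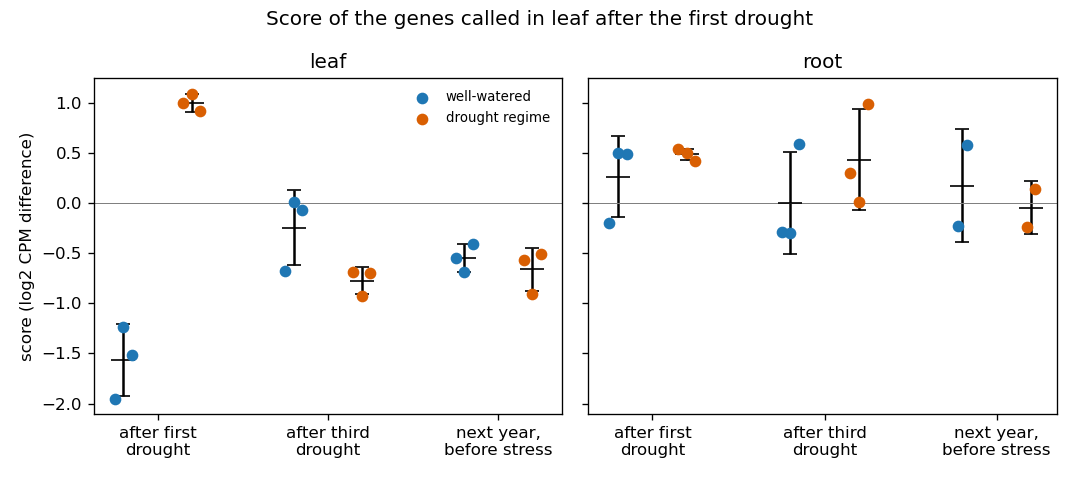
Score of the genes called in leaf after the first drought, in log2 CPM (mean of the genes that rose minus mean of the genes that fell), for each library; points are libraries, horizontal bars group means and vertical bars the SD. In leaf after the first drought the well-watered mean is -1.57 and the drought mean 1.00, and after the third drought they are -0.24 and -0.77.

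A score per library, the mean log2 CPM of the genes that rose minus that of the genes that fell, showed where these genes stood. It was -1.57 ± 0.36 in well-watered and 1.00 ± 0.09 in drought leaves after the first drought (SD, n = 3 each), on the libraries used to choose the genes. After the third drought it was -0.24 ± 0.38 and -0.77 ± 0.14, with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow. In the next year it was -0.55 ± 0.14 and -0.66 ± 0.22 (exact two-sided permutation p = 0.6). These permutations ignore the sowing blocks. Within each of the 3 blocks drought lay below well-watered at both samplings, though block 1 was nearly tied at both. For the third drought the pairs, drought first, were -0.692 and -0.677, -0.931 and 0.016, and -0.695 and -0.071. The well-watered library of block 2 there has an unusual make-up. For the next year the pairs were -0.567 and -0.549, -0.907 and -0.689, and -0.508 and -0.407. The smallest exact sign-flip p that 3 blocks allow is 0.25.

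The change of the leaf response between the droughts was tested directly. The drought effect differed between the first and the third drought for 1862 genes, more positive at the third for 1143 and more negative for 719 (edgeR, adjusted p under 0.05). Of these, 1771 were among the genes called after the first drought, in a comparison that shares those libraries, and 98.4% had the larger effect at the first drought.

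The 4 genes with the largest differences in either direction, 2 each, were scarce, with group means of at most 5.01 CPM. Each lost its call in 7 to 11 of its 18 or 19 alternatives, so they are not described singly. The count of 1862 fell to 755 without well-watered block 1 of the first sampling, 603 without well-watered block 2 of the third, 1129 and 957 without drought blocks 1 and 2 of the first, and 782 without drought block 2 of the third; with only the 4 groups fitted it was 173 more positive and 61 more negative, and DESeq2 gave 3743.

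**Figure D2:**
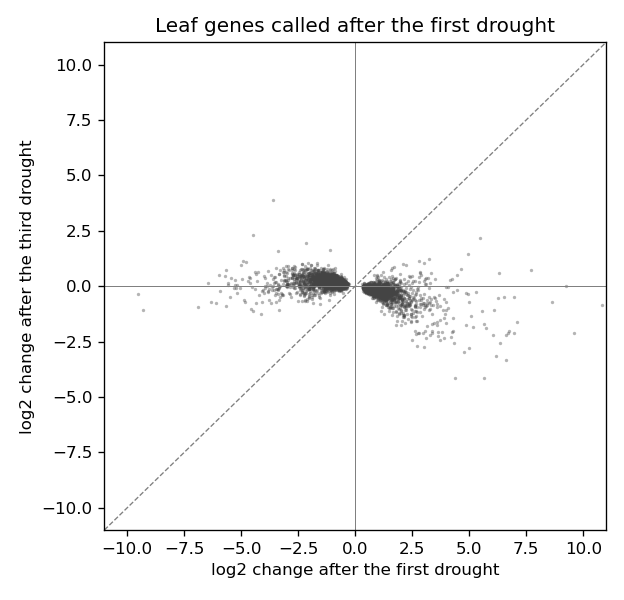
Log2 change (drought against well-watered leaves) after the third drought against that after the first, for the 3812 genes called after the first drought; each point is a gene and the dashed line marks equal changes. The points lie along the horizontal axis, with a slope through 0 of -0.158.

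In the next year, before a new stress, no leaf gene passed the test in plants that had gone through the 3 droughts. The median log2 change was -0.08 among the genes that had risen after the first drought and 0.04 among those that had fallen (camera adjusted p = 8.34e-05 and 0.162, adjusted p = 0.514 and 0.757 with an estimated correlation). Of 32307 genes, 356 had an unadjusted p under 0.05; edgeR called 0 and DESeq2 called 1. The change of the leaf effect from the third drought to the next year gave 0 calls with edgeR, 493 genes at an unadjusted p under 0.05, and 1 call with DESeq2.

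Well-watered leaves changed between samplings without drought. From the first to the third sampling 2621 genes rose and 2255 fell (edgeR, adjusted p under 0.05). Of these, 1954 rose and 609 fell by at least 2-fold. Of the genes named for the first drought, MD06G1227300 stood at 0.699 ± 0.433 and then 22.7 ± 6.12 CPM in well-watered leaves and MD08G1062400 at 0.0228 ± 0.0202 and 2.9 ± 1.22 CPM, the direction of the drought change. MD17G1140600 stood at 6.85 ± 4.27 and then 25.6 ± 23.9 CPM and MD09G1154000 at 5.28 ± 4.08 and 23.7 ± 22.4 CPM, against that direction. Of all genes called after the first drought, 83.9% moved in the direction of the drought change. Genes called in both comparisons numbered 792 higher, 505 lower and 18 in opposite directions. Both comparisons share the well-watered libraries of the first sampling, which alone favours the same sign. The count of 4876 was 894 without block 1 and 1450 without block 2 of the first sampling, 2047 without block 2 and 2960 without block 3 of the third. Fitting these 6 libraries alone called only 5 genes, all among the 4876, so the count depends on having the other leaf groups in the fit. The smaller fit has fewer libraries to estimate the spread, and its filter and scaling were also set anew. These were not separated.

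In roots after the first drought no gene passed the test. The leaf genes that rose with the first drought had a median log2 change of 0.18 in root, and those that fell -0.07. Camera gave adjusted p = 4.82e-09 and 0.0658, and adjusted p = 0.514 and 0.757 with an estimated correlation. Within blocks 1, 2 and 3 the score, drought first, was 0.539 and -0.199, 0.497 and 0.5, and 0.425 and 0.494. Only in block 1 was it higher in drought. Of 33541 genes tested, edgeR and DESeq2 called 0, and 340 had an unadjusted p under 0.05. The 6 libraries did not group by regime, since for only 1 of the 6 was the most similar library from its own group, against 6 of 6 in leaf.

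In roots after the third drought no gene passed the test with edgeR, 936 genes had an unadjusted p under 0.05, and DESeq2 called 1. The leaf genes that had risen showed a median log2 change of 0.18 and those that had fallen -0.18. Camera gave adjusted p = 1.61e-08 and 4.82e-09, and adjusted p = 0.514 for both with an estimated correlation (0.483 for both with the replicate block). Within each of the 3 blocks the score was higher in drought than in well-watered roots (0.302 and -0.291, 0.015 and -0.3, 0.988 and 0.591), where the smallest exact sign-flip p that 3 blocks allow is 0.25. In the next year edgeR called 0 root genes, 739 had an unadjusted p under 0.05, and DESeq2 called 2, with 2 libraries per group. The regimes there share only block 3, so they are partly confounded with the sowing block. In that block the score was 0.144 in drought and 0.576 in well-watered roots, the other way from the third sampling. The leaf sets had medians of -0.18 and 0.07 (camera adjusted p = 7.74e-06 and 0.152, adjusted p = 0.514 and 0.757 with an estimated correlation). The change of the root effect from the first to the third drought gave 0 calls with either tool and 408 genes at an unadjusted p under 0.05. From the third drought to the next year there were 0 calls with edgeR, 877 genes at an unadjusted p under 0.05 and 1 call with DESeq2. Well-watered roots of the third against the first sampling gave 0 calls with edgeR, 1872 genes at an unadjusted p under 0.05 and 26 calls with DESeq2.

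The drought effect was compared between leaf and root in a joint fit. After the first drought it differed for 56 of 35665 genes, more positive in leaf for 11 and more negative for 45 (edgeR, adjusted p under 0.05). With the replicate block as a term it differed for 110, including the same 56. Scaling by RLE gave 29 genes, split 10 to 19, and DESeq2 gave 454. The count was 11, 116 and 22 without well-watered leaf blocks 1, 2 and 3, 18 and 36 without drought leaf blocks 1 and 2, 24 without well-watered root block 3, and 18 and 13 without drought root blocks 1 and 3. After the third drought it differed for 0 genes with edgeR and DESeq2, and 1310 had an unadjusted p under 0.05. Since no gene was called after the third drought or in root, the lists of called genes from different droughts or tissues shared 0 genes.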

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

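The tests of the slope and of exchanged labels, and the splits of the comparisons of a single sampling between regimes, were chosen or run only after the results had been seen, as was the comparison with splits that part every block.

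The leaf drought effect differed between the first and the third drought for 1862 genes, which marked it as a difference between samplings. A wider spread that hides a response of the first size would need a slope of the later on the earlier effects near 1, but over the 3812 genes it was -0.158, and -0.231 to -0.117 over the 6 fits leaving out a library of the third sampling. Without the well-watered library of block 2, which has an unusual make-up, edgeR called 0 genes after the third drought, as with it (727 at an unadjusted p under 0.05, 0 with DESeq2), and exchanging the labels of a single block also gave at most 0. Several accounts stay open: chance, a shift common to the well-watered leaves of the first sampling, whose score of -1.57 lay below the -0.24 and -0.55 of the later well-watered leaves on genes chosen with those libraries, and a biological difference that may be acclimation, plant age or season and was not tested.

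Of 100 splits drawn for this change from the first to the third drought in leaf, 5 gave as many genes, the real one included, so chance is not excluded; the highest other gave 5402. All 4 others kept the regimes of the first sampling whole and so carry that drought effect, and none of the 4 parts every block. Of the 15 drawn that part every block at both samplings, the labels gave the highest count and the next gave 612, but 15 are too few for a share under 0.05.

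The drought effect differed between leaf and root after the first drought for 56 genes, which marked it as a difference between tissues. Of 60 splits drawn, 11 gave as many, with 1169 in the highest other, so chance is not excluded. Of the 10 others, 6 kept the leaf regimes whole and so carry the leaf drought effect, and the highest of those that did not was 934, which points to structure beyond the regimes. Of the 12 drawn that part every block in both tissues, 3 others gave as many, with 1169 in the highest. Without both block 2 root libraries of the first sampling, a choice made after seeing the data, 215 genes differed, of which 42 were among the 56.

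For single comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In leaf after the first drought the labels gave 3812 genes, as 1 split, and the highest other 2, with 0 in the others that part every block. In leaf after the third drought the labels gave 0 and the highest other 278, from a split that does not part every block, while the 4 splits that part every block gave 0. The next year gave 0 in leaf for all 10 splits. Root after the third drought gave 0 against 2 in the highest other. Well-watered leaves of the third against the first sampling gave 4876, as 1 split, against 0, and well-watered roots 0 against 0. Where the labels called 0 genes every split gives at least as many by construction, so these tallies (10 of 10, 100 of 100 and 60 of 60) test nothing, and only the highest other is of use. For the change from the third drought to the next year in leaf, with 100 splits drawn, it was 33. For the change from the first to the third drought in root, with 100 drawn, it was 2745, and 318 among those that part every block. For leaf against root after the third drought, with 60 drawn, it was 2047, and 0 among those that part every block. Counts that high point to structure among the libraries that the regimes do not describe.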

How the results depend on the processing

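The genes named for the first drought in leaf kept their direction under every alternative run, while the number of called genes there moved. The absence of calls in root after the first drought and in leaf after the third held under every alternative. Exchanging the block 2 root labels of the first sampling, a split and not among these alternatives, called 767 genes. Leaving out both block 2 root libraries, both block 3 leaf libraries or the unusual leaf library was chosen after seeing the data, as were the set tests.

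For leaf after the first drought (3812), a fold threshold gave 2148, DESeq2 5843 and the 6 libraries alone 1182; leaving out a library gave 1461 to 3903. For the leaf change from the first to the third drought (1862), DESeq2 gave 3743 and the 4 groups alone 173 more positive and 61 more negative (2.3e+02 in all); leaving out a library gave 603 to 2458. For well-watered leaves over time (4876), a fold threshold gave 2563 and the 6 libraries alone 5; leaving out a library gave 894 to 6227. For leaf against root after the first drought (56), DESeq2 gave 454, the 4 groups alone 35, RLE 29, the replicate block 110, and leaving out both block 2 root libraries 215; leaving out a library gave 11 to 116. After the third drought, leaving out a library gave 0 to 2 there. DESeq2 gave 1 call for leaf in the next year, for the leaf change to the next year, for the root change to the next year and for root after the third drought. It gave 2 for root in the next year and 26 for well-watered roots over time. Leaving out a library gave 0 to 1 for leaf in the next year and for the leaf change to the next year. The root change from the first to the third drought gave 1 without both block 2 root libraries. Causes were not tested, except that fits of fewer groups have fewer libraries to estimate the spread.

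At the third drought the medians of the leaf sets, -0.186 and 0.19, kept their sign under all 15 alternatives each. The estimated correlation and a camera test on ranks are among these and leave the median unchanged by construction. Leaving out a library gave -0.264 to -0.135 and 0.14 to 0.313. With an estimated correlation the camera adjusted p was 0.12 for both sets. The refits gave unadjusted camera p as low as 2.91e-25 and 1.21e-43. Apart from leaf against root after the first drought (56 to 110, the 56 among them), the replicate block moved counts by less than 1.5 times but changed which genes were called: it gave 3969 after the first drought in leaf (3463 of the 3812), 1872 for the leaf change from the first to the third drought (1601 of the 1862) and 5100 for well-watered leaves over time (4487 of the 4876). Among named genes, MD08G1062400 and MD17G1140600 lost their call in 1 and 3 of 14 alternatives, with adjusted p up to 0.0589 and 0.0731 (from 6.31e-06 and 4.62e-05). No direction reversed. The gene lists fixed in advance were not run, for want of gene names. Root comparisons of the next year rest on 2 libraries per group that share only block 3. In simulated counts at that size 4.48% of genes changed 2-fold were called, drawn from the more abundant of 33178 genes.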

Other observations

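The tests on exchanged root labels, root states, the unusual leaf library and the shared controls were chosen only after the results had been seen, as were the sets of tissue-predominant genes. The test on neighbouring identifiers was not.

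Genes that are at least 32-fold higher in next-year well-watered roots than leaves (2184) or the reverse (2093) were followed through the droughts. In leaf after the first drought, 1657 of all 32307 tested genes rose and 2155 fell. Of 838 tested root-predominant genes 52 rose, a share near that of all genes, and 14 fell. Their median log2 change was 0.59 (camera adjusted p = 0.000373, adjusted p = 0.675 with an estimated correlation). The root-predominant genes are scarce in leaf, together at most 0.734% of the counts of a leaf library. Of 2070 leaf-predominant genes, 141 rose and 274 fell (median -0.07, camera adjusted p = 0.0658, adjusted p = 0.514 with an estimated correlation). After the third drought in leaf the root-predominant genes went the other way, with a median of -0.23 and 0 called (camera adjusted p = 2.48e-07, adjusted p = 0.514 with an estimated correlation), and the leaf-predominant genes had a median of 0.04 (camera adjusted p = 0.197, adjusted p = 0.696 with an estimated correlation). In root after the first drought the root-predominant genes had a median of -0.26 with 0 called (camera adjusted p = 5.33e-09, adjusted p = 0.514 with an estimated correlation), and after the third -0.15 with 0 called (camera adjusted p = 0.000879, adjusted p = 0.514 with an estimated correlation). The leaf-predominant genes had root medians of -0.07 and -0.04 (camera adjusted p = 0.144 and 0.432, adjusted p = 0.696 and 0.757 with an estimated correlation). No set of tissue-predominant genes passed with an estimated correlation.

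Called leaf genes tended to stand beside each other in identifier order. Among 31250 tested identifiers, 358 adjacent pairs were called in the same direction after the first drought, against a mean of 219.9 and a highest of 277 in 10000 random orders (permutation p = 1e-04, one-sided, the smallest they can give). Pairs called in opposite directions numbered 180, against a mean of 212.1. Neighbouring genes may respond together, though reads divided between similar copies could also give such pairs and this was not tested.

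The log2 changes of the first drought in leaf and those of well-watered leaves from the first to the third sampling share 3 control libraries, which alone makes them covary. The covariance of both sets of log2 changes was 0.172, and 50 simulations with no effect, sharing the same controls, gave a mean of 0.043 and a highest of 0.046. The correlation was 0.52, which the highest simulated value of 0.52 reached, so it shows nothing beyond the sharing. The simulated genes vary independently of each other, so the larger covariance may come from a shift common to the 3 shared control libraries, which cannot be told apart from a change with age.

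In root after the first drought the labels gave 0 called genes with edgeR and DESeq2 (340 at an unadjusted p under 0.05), whereas 1 of the 10 splits gave 767, namely the split that exchanges the block 2 labels and so parts every block; 10 splits are too few for a share under 0.05, and all 10 give at least 0 by construction. Exchanged labels could produce this. Within the 3 blocks of the third sampling the score of those genes was higher in drought by 0.835 ± 0.377 on average (SD). The exact two-sided sign-flip p was 0.25, the smallest possible, and the blocked rotation test fry gave p = 0.553 and 0.556. Fry is limma's test of whether a set moves in one direction, here the genes higher and lower in that split. Fry missed what exchanged labels had been taken to require. But its spread came from a fit of all root groups under the given labels. There block 2 of the first sampling scored 1.08 in well-watered and -3.17 in drought roots. Blocks 1 and 3 scored -3.5 and -3.48 in well-watered, and 0.57 and 0.1 in drought roots. The genes were chosen by exchanging block 2, so it widens their spread and fry cannot decide. The single next-year pair, of block 3, differed by 0.357. A root state unrelated to watering could also produce the 767 calls. On the first principal component, libraries of the same regime at the third sampling ranged over 1.28 times the gap between the exchanged groups. On the score itself that range was 0.42 times the gap, but the score was built from genes chosen for the gap. These explanations cannot be told apart with 3 blocks, and a real drought response of the root stays open.

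The well-watered leaf library of block 2 at the third sampling held 15.7% of its counts in MD16G1283000, named here after its values were seen, against 0.201% to 1.93% in the other leaf libraries. In this library 90 genes were at least 4 times above every other leaf library of that sampling and took 29.5% of its counts. Root RNA is argued against by the share of root-predominant genes, 0.382%, within the 0.155% to 0.532% of the other leaf libraries of the sampling and below the lowest root library at 7.85%. A candidate explanation is extra input of a fixed set of transcripts. The second most abundant gene of this library stood at 0.33 of the first, inside the 0.321 to 0.398 of those other libraries. However, the ratio was 0.318 to 0.51 in all other libraries of both tissues. It therefore cannot tell extra input from anything else that scales both genes, and it covers only these genes of the set. No biological explanation was tested.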
